A study of Homo sapiens with 42 samples.

How the data were processed

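PolyA RNA of 42 human meningioma tumors was sequenced from TruSeq v2 libraries, per the labels' protocols. All 42 carry 1 tissue label, so they form 1 group and no contrast between groups was made. Nothing in the labels says whether any of them share a patient, so the p-values measure the spread between these samples. Per the submitters' processing notes, reads were aligned with HISAT2 and quantified with Cufflinks on the hg19 build; versions are not given in the sources used here.

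The authors deposited 1 table of FPKM values, fragments scaled by transcript length and by the mapped total, with 1 line per RefSeq transcript and locus. It holds 62858 transcript lines for 59343 accessions, of which 58343 (98.3%) were matched to a gene symbol through the RefSeq gene table of assembly GRCh38.p14. Because that assembly differs from hg19, it served only for symbols, chromosomes and the order and overlap of genes, and no coordinates are given. FPKM of a gene was taken as the sum over its transcripts, which gave 26591 genes, 18876 of them protein-coding. Genes of the Y chromosome and transcripts of X inactivation were left out from the start.

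FPKM keep no read counts, so the depth of each library is unknown and no counting interval is given. A value of exactly 0 can be a failed estimate: among 1154 protein-coding genes with a median of at least 50 FPKM, 17 were listed at 0 in at least 1 tumor. Such genes are described as listed at 0. Column sums were not equal, and 1 accession without a gene symbol took a median of 32.8% of the summed FPKM (range 5.94% to 87.0%). No column of the table belonged to another sample, and no pair of tumors had identical values.

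Tests were run on log2(FPKM + 1). On this scale a change of a gene with low FPKM is understated. Genes entered where FPKM reached 1 in at least 10 tumors, which left 13951 genes, 12635 of them protein-coding. For FOXM1 and for PGR, limma (version 3.58.1, R 4.3.3) fitted each other gene on the standardised log2 value of that gene, with a trended prior, and Benjamini-Hochberg adjustment with a threshold of 0.05. The slope is the log2 change per SD of FOXM1 or PGR. Gene lists were tested on the FOXM1 fit with camera, at a preset correlation of 0.01 and with the correlation estimated, and with fry. Camera compares a list with the other genes. Fry asks whether the genes of a list move, on balance, in 1 direction.

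A list score is the mean of the z-scores of its members over tumors, for members with a mean log2 value of at least 0.2, with at least 3 members, and a gene in both lists of a pair was left out of the second. Relations over tumors are given as Pearson's r and Spearman's rho, each with a two-sided permutation p from 100000 resamples and Benjamini-Hochberg adjustment within its family. The smallest p these permutations can give is 1e-05. Each was repeated without the 2 tumors farthest from the median of the first measure, leaving 40. Chromosome scores are the median centred log2 value of the genes of each autosome, with chromosome 1 split at 130 Mb. List coherence is the median pairwise rho of the members, set against 10000 random lists of the same size matched on mean expression. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 was used.

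The 27 gene lists, the tests, the filter, the pseudocount and most alternatives were fixed before the data were examined. So was the rule for the genes named: FOXM1, PGR, NF2 and list members, the 10 genes with the largest mean share of summed FPKM, the 20 most variable genes, and for FOXM1 and PGR the 12 genes with the largest slope in each direction among those past the threshold with and without the 2 farthest tumors. Small RNA genes, clone names and antigen receptor segments are not named. Chosen after the data were seen were the sum over transcripts, the demand that a relation pass the threshold by both r and rho, the removal of a GC trend, the counting of repeated accessions once, the omission of genes with a doubtful 0, and a split of the tumors.

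That split stands in for a batch, since the labels give none. SNORD141A, a small nucleolar RNA that polyA libraries are not built to capture, lay between 4771 and 71224 FPKM in 27 tumors and between 14.2 and 712 FPKM in 15, and relations were recomputed within each part. The filter within each part was scaled to its number of tumors. GC content came from GENCODE 29 and was known for 12538 (89.9%) of the genes tested. Alternatives tried were pseudocounts of 0.1 and 0.01, rescaling by upper quartile or median ratio, no filter or a filter of 21 tumors, other covariates, and rank in place of level. Chromosome scores were also set against 1000 sets of genes of other chromosomes matched on GC content, on FPKM as deposited, with the upper percentile of their SDs as bound. The same test after GC removal was run and is not used, since matched sets cannot spread there. For genes listed at 0, the share of all values under 1 FPKM was replaced by the lowest value of each gene. The choice of the genes bounds the former directly, though it also favors higher lowest values.

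The procedures were tested on simulated data. Of 200 pairs of measures over 42 simulated tumors with no relation, r passed 0.05 in 3% and rho in 4%. At a true r of 0.5 the shares were 86.5% and 81%, and at 0.8 both were 100%. For the FOXM1 fit, 13951 genes were simulated with 200 changed. limma recovered 31% of those with a slope of 0.5 SD and 99% of those with a slope of 1 SD, with no sign error. The 9 false calls were 6.47% of the calls. The simulated genes varied independently of each other, unlike the real ones, so false calls from trends shared by genes were not tested.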

Results

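Expression was measured by polyA RNA sequencing in 42 meningiomas, tumors of the coverings of the brain, which the labels place in 1 group. The summed FPKM per tumor ranged from 632530 to 2516490 with a median of 951191. A median of 12557 genes per tumor reached 1 FPKM (range 10674 to 13465, SD 596). Spearman's rho between pairs of tumors ran from 0.833 to 0.930 with a median of 0.897. The depth of the libraries is unknown, since only FPKM were used.

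The tumors expressed most listed genes of the arachnoid and meningothelial lineage at high levels, with ALDH1A2 lowest at a median of 2.21 FPKM. All 16 members of that list reached 1 FPKM in at least 10 tumors, and 11 did so in all 42. The intermediate filament gene VIM had a median of 2747 FPKM, the chaperone gene CLU 2496 FPKM and the prostaglandin D synthase gene PTGDS 2296 FPKM, with quartiles of 590 and 6342 FPKM for PTGDS. The junction genes DSP and CDH1 had medians of 54.4 and 43.0 FPKM, and SSTR2, the somatostatin receptor used in meningioma imaging, had a median of 12.6 FPKM. Of 13 fibroblast and collagen genes, 7 reached 1 FPKM in all 42 tumors. Their medians ran from 537 FPKM for fibronectin (FN1), 465 FPKM for COL1A2 and 339 FPKM for SPARC to 3.54 FPKM for LUM, 2.62 FPKM for THBS2 and 0.629 FPKM for the growth factor receptor PDGFRA.

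Myeloid genes were present throughout. Of 14 macrophage and microglia genes, 11 reached 1 FPKM in all 42 tumors, with medians of 235 FPKM for the complement gene C1QA, 177 FPKM for the adaptor TYROBP and 26.3 FPKM for the scavenger receptor CD163. Lymphocyte genes were low. The T cell receptor subunit CD3E had a median of 1.33 FPKM, no member of the T cell list reached 1 FPKM in all tumors, and the median over the members of the B and plasma cell list was 0.0900 FPKM. Among hormone receptors, the median was 1.43 FPKM for the progesterone receptor PGR (quartiles 0.516 and 2.81; 23 tumors at 1 FPKM or more) and 0.461 FPKM for the estrogen receptor ESR1. The receptor tyrosine kinase genes PDGFRB, ERBB2 and FGFR1 had medians of 53.2, 33.3 and 32.5 FPKM, and EGFR 6.94 FPKM.

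Proliferation genes were low in most tumors. FOXM1, a transcription factor that drives genes of the G2 and M phases, had a median of 1.97 FPKM (quartiles 1.24 and 2.87, range 0.389 to 21.3) and reached 1 FPKM in 34 tumors. MKI67, the gene of the Ki-67 antigen, had a median of 0.533 FPKM and reached 1 FPKM in 12 tumors, while UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, had a median of 5.50 FPKM. Of the genes recurrently mutated in meningioma, NF2 had a median of 2.92 FPKM, the kinase AKT1 58.4 FPKM, and the telomerase gene TERT had a median of 0 FPKM.

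**Figure D1:**
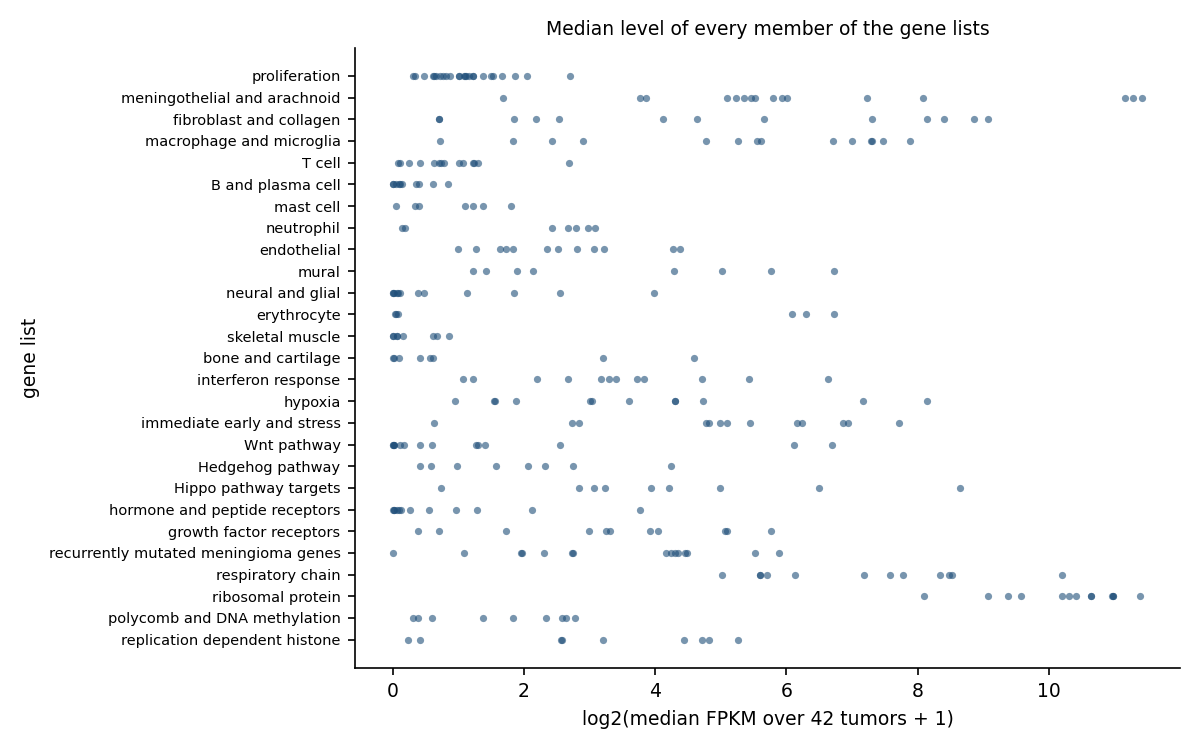
Each point is the median FPKM over 42 tumors of 1 member of a gene list, on a log2(FPKM + 1) axis, with the lists as lines. Ribosomal protein genes lie highest as a group (median of members 1364 FPKM), and most genes of the B and plasma cell list lie near 0.

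By mean share of the summed FPKM the leading named genes were PTGDS (0.768%, SD 1.27), the actin-binding peptide gene TMSB10 (0.558%, SD 0.339) and RPLP1 (0.483%, SD 0.271), followed by RPL37A, RPS27, RPS18, RPL13AP5, VIM and CLU. The SD of log2(FPKM + 1) was largest for C19orf33 (3.51), BOLA2 (3.43), the interferon-induced gene IFI27 (3.36), the carbonic anhydrase gene CA3 (3.26), EIF3C (3.20), PTGDS (3.07) and DAPL1. The imprinted RNA H19 had an SD of 2.95, the enkephalin precursor PENK 2.91, CD177 2.79, the methyltransferase NNMT 2.64 and EGFL6 2.58. RPL21P28, BACC1, PRG4, NT5DC2, DYNLRB1, SMIM19, DYNC2I2 and ENC1 complete the 20. Many of the 20 were listed at 0 in several tumors, and their spread includes these values: RPL21P28 in 31, DYNC2I2 in 24, EIF3C in 23, BACC1 in 19, IFI27 and NT5DC2 in 18, PRG4 in 17, SMIM19 in 14, DYNLRB1 and ENC1 in 13, BOLA2 in 10 and C19orf33 in 7.

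FOXM1 and genes of proliferation went together closely. FOXM1 and the score of the proliferation list, which does not contain it, had r = 0.939 and rho = 0.905 over 42 tumors (permutation p = 1e-05 for each, the smallest the permutations can give). Without the 2 tumors farthest from the median of FOXM1, r was 0.900. Within the 27 tumors with high SNORD141A r was 0.927, and within the 15 with low SNORD141A it was 0.953. This was 1 relation tested on its own. It was chosen because the study of these tumors is known to address FOXM1 and meningioma proliferation. Its p-value is therefore no independent support for that link.

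**Figure D2:**
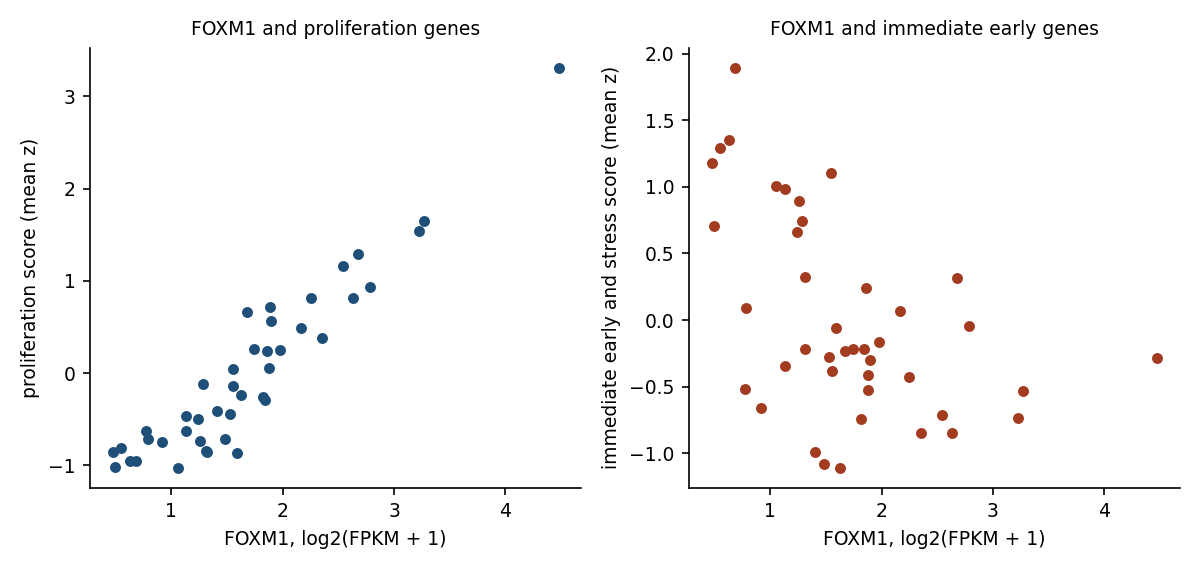
Each point is 1 of 42 tumors, with FOXM1 as log2(FPKM + 1) on the x axis and a list score (mean z-score) on the y axis. The proliferation score rises with FOXM1 (r = 0.939), and the immediate early and stress score is lower at high FOXM1 (rho = -0.520).

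Over all genes, UBE2C was higher by 1.44 log2 per SD of FOXM1 (SE 0.12, n = 42, limma adjusted p = 1.85e-12), the securin gene PTTG1 by 1.07 (SE 0.10) and the thymidine kinase TK1 by 1.02 (SE 0.10). The mitotic kinase AURKB was next (SE 0.09). TPX2, KIF20A, TOP2A, PCLAF, BIRC5 and SPC24, genes of the spindle, chromosome segregation and DNA replication, and CDKN3 had slopes from 0.92 down to 0.86. The leptin receptor LEPR fell by 1.14 per SD (SE 0.26, adjusted p = 0.00480), the nuclear receptor NR4A1 by 1.06 (SE 0.23), the antiproliferative gene BTG2 by 1.02 (SE 0.16) and the MAP kinase phosphatase DUSP1 by 1.01 (SE 0.17). NR4A2 and NR4A3, CSRNP1, ATF3 and ZFP36, all induced early by growth factors or stress, also fell, with slopes between -0.91 and -0.70, as did THSD4 (-0.74). The antisense gene BABAM2-AS1 (-0.76) overlaps BABAM2 and CHMP1B (-0.71) lies inside GNAL, each by the RefSeq table of GRCh38.p14. KIF20A overlaps CDC23, and LEPR overlaps LEPROT. KIF20A was listed at 0 in 18 tumors and BABAM2-AS1 in 29. BOLA2 had the largest positive slope (1.73, SE 0.45, adjusted p = 0.0193), but it has near-identical copies and was listed at 0 in 10 tumors.

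All 23 tested proliferation genes rose with FOXM1, and 23 did when adjusted over the list alone. MKI67 had a slope of 0.61 (SE 0.05) and MYBL2 0.86 (SE 0.07). Of 7 polycomb and DNA methylation genes, 4 rose and 3 did not pass (4 adjusted over the list alone): the histone methyltransferase EZH2 (0.47, SE 0.07), UHRF1, which recruits DNA methyltransferase to replicated DNA (0.56, SE 0.05), and the methyltransferases DNMT1 and DNMT3A (both 0.24, SE 0.07). DNMT1 and DNMT3A did not pass without the 2 farthest tumors, and passed in 10 and 14 of 17 alternatives. Of 13 immediate early and stress genes, 5 fell (DUSP1, ATF3, ZFP36, FOS at -0.73 and JUNB at -0.71), 0 rose and 8 did not pass. The number was 10 adjusted over the list alone. The 9 genes of the list of Hippo pathway targets include YAP1, TEAD1 and LATS2, which are parts of the pathway itself. Of these 9 genes, 3 fell (CCN2 at -0.90, CCN1 at -0.77 and AMOTL2 at -0.42) and 6 did not pass. Adjusted over the list alone 6 were negative. None of the 3 passed without the 2 farthest tumors (past in 13, 14 and 13 of 17 alternatives).

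Of 16 meningothelial genes LEPR alone passed, with 3 negative adjusted over the list alone. Of 13 fibroblast and collagen genes FAP alone passed (0.59, SE 0.18; 1 adjusted over the list alone), and it did not without the 2 farthest tumors (past in 9 of 16 alternatives). No member of any other list passed over all genes. Adjusted over the list alone, the hypoxia list had 1 positive and 1 negative, hormone and peptide receptors 2 negative, and growth factor receptors, recurrently mutated genes and the Wnt pathway 1 negative each. The remaining lists had 0: macrophage and microglia, T cell, B and plasma cell, mast cell, neutrophil, endothelial, mural, neural and glial, erythrocyte, skeletal muscle, bone and cartilage, interferon response, Hedgehog pathway, respiratory chain, ribosomal protein and replication dependent histone. PGR had a slope of -0.32 on FOXM1 (SE 0.13, adjusted p = 0.137), and RHNO1, which shares the FOXM1 locus, 0.08 (SE 0.08, adjusted p = 0.603).

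Camera with a preset correlation placed 5 lists apart from other genes: proliferation (adjusted p = 1.10e-91) and polycomb and DNA methylation (0.000537) upward, and immediate early and stress (3.36e-08), Hippo pathway targets (0.000233) and growth factor receptors (0.0137) downward. With an estimated correlation proliferation alone passed (adjusted p = 3.01e-07). The adjusted p with an estimated correlation was 0.164 for polycomb and DNA methylation, 0.164 for immediate early and stress, 0.184 for Hippo pathway targets and 0.184 for growth factor receptors. Fry's directional test passed for these 5 (adjusted p = 5.17e-19, 3.42e-05, 0.00507, 0.0136 and 0.0185) and for hormone and peptide receptors (0.0233).

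Over 13950 genes the FOXM1 fit called 416 positive and 127 negative, of which 146 and 33 also passed without the 2 farthest tumors. After upper quartile rescaling the split was 628 to 388, after median ratio rescaling 1008 to 648, and after removal of the GC trend 648 to 402. Within the 27 tumors it was 190 to 36 and within the 15 tumors 79 to 0. Of the 24 genes named, 18 passed within the 27 tumors, and 11 of 23 with a value passed within the 15.

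**Figure D3:**
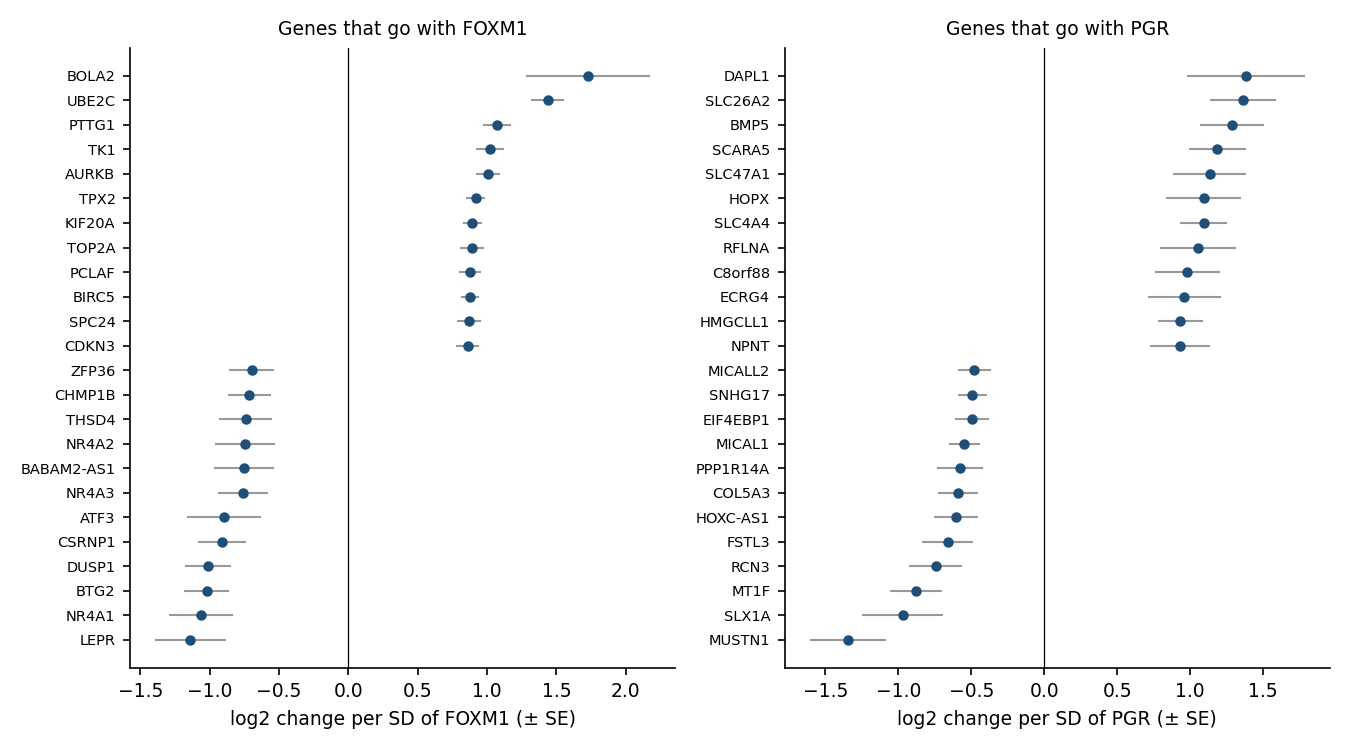
Points are limma slopes over 42 tumors in log2 change per SD of FOXM1 (left) or PGR (right), with bars of 1 SE, for the 12 genes named in each direction. UBE2C has a narrow error at 1.44, and BOLA2 a wide one at 1.73.

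PGR is a routine marker of meningioma. The sulfate transporter SLC26A2 was higher by 1.36 log2 per SD of PGR (SE 0.23, n = 42, limma adjusted p = 0.000982), the bone morphogenetic protein BMP5 by 1.29 (SE 0.22), the ferritin receptor SCARA5 by 1.19 (SE 0.19), the efflux transporter SLC47A1 by 1.13 (SE 0.25) and the bicarbonate cotransporter SLC4A4 by 1.09 (SE 0.16). DAPL1 had the largest slope (1.38, SE 0.40, adjusted p = 0.0451), and HOPX (1.09), RFLNA (1.05), C8orf88 (0.98), ECRG4 (0.96), HMGCLL1 (0.93) and NPNT (0.93) complete the 12. The metallothionein MT1F fell by 0.88 (SE 0.18, adjusted p = 0.00580), the activin-binding gene FSTL3 by 0.66 (SE 0.18) and the collagen gene COL5A3 by 0.59 (SE 0.14). RCN3 (-0.74), HOXC-AS1 (-0.60), PPP1R14A (-0.58), MICAL1 (-0.55), EIF4EBP1 (-0.49), SNHG17 (-0.49) and MICALL2 (-0.48) also fell. MUSTN1 had the largest negative slope (-1.34, SE 0.26, adjusted p = 0.00459), but it overlaps another gene and was listed at 0 in 19 tumors, so its value is uncertain. The same holds for SLX1A (-0.97), from a duplicated locus and at 0 in 6 tumors, and for C8orf88, at 0 in 7. HOXC-AS1 was at 0 in 17.

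Among the lists, 2 of 16 meningothelial genes rose with PGR, the desmosome gene DSP (0.73, SE 0.17, adjusted p = 0.0163) and the cadherin CDH1 (0.71, SE 0.17), and 14 did not pass; adjusted over the list alone 6 were positive and 1 negative. FGFR3 (0.66, SE 0.15, adjusted p = 0.0109) was the 1 growth factor receptor of 10 that passed, and KIT (0.54) the 1 mast cell gene of 6 (1 and 2 positive adjusted over the list alone). In the hypoxia list NDRG1 rose (0.45) and PFKFB4 fell (-0.30) among 12 (1 and 1 adjusted over the list alone). TET2 rose (0.22) among 7 polycomb and DNA methylation genes (2 adjusted over the list alone). Of 23 proliferation genes CDC20 fell (-0.44) and 22 did not pass, with 8 negative adjusted over the list alone. FOXM1 itself had a slope of -0.30 on PGR (SE 0.12, adjusted p = 0.116). No member of another list passed. Adjusted over the list alone, the Wnt pathway, Hippo pathway targets, hormone and peptide receptors and recurrently mutated genes had 1 positive each and the others 0.

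The PGR fit called 358 positive and 121 negative of 13950 genes, and 166 and 42 of them also passed without the 2 farthest tumors. The split was 275 to 185 after upper quartile rescaling, 170 to 138 after median ratio rescaling and 87 to 24 after removal of the GC trend. Within the 27 tumors it was 40 to 7, with 8 of the 24 named genes past the threshold, and within the 15 tumors no gene passed. Of the named genes 12 of 22 with a GC value passed after removal of the GC trend, and DAPL1, HOPX, C8orf88, ECRG4, SLX1A, RCN3, FSTL3, COL5A3, PPP1R14A and MICALL2 did not. With PC1 as a covariate 8 of 24 passed, while the slopes stayed at a median of 0.872 of their size (range 0.668 to 1.17), with a median SE of 0.20 against 0.19 before. HOPX, for example, went from 1.09 (SE 0.26) to 1.16 (SE 0.28) and did not pass.

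Gene groups varied together in several blocks. Of 351 pairs of list scores, 22 passed by both r and rho with a positive sign and 0 with a negative sign (59 and 4 at an unadjusted permutation p under 0.05; 1 negative by r alone and 1 by rho alone). T cell and B and plasma cell scores had r = 0.719 and rho = 0.662 (adjusted permutation p = 0.000877 and 0.00175). Their r was 0.585 without the 2 farthest tumors, 0.680 within the 27 tumors and 0.785 within the 15. The B and plasma cell score rests on genes near the floor, as 2 of the 10 in its list reached 1 FPKM in at least 10 tumors. CD27, in that score, was listed at 0 in 33 tumors. Proliferation and polycomb and DNA methylation scores had r = 0.675 and rho = 0.624 (adjusted p = 0.000877 and 0.00234; 0.515 without 2 tumors, 0.632 and 0.796 within the parts). Growth factor receptors went with hormone and peptide receptors (r = 0.652, rho = 0.606; 0.649 without 2 tumors, 0.519 and 0.811 within the parts) and with recurrently mutated genes (r = 0.675, rho = 0.569; 0.617 without 2 tumors, 0.603 and 0.782 within the parts). Macrophage and neutrophil scores had r = 0.581 and rho = 0.676 (0.587 without 2 tumors, 0.581 and 0.690 within the parts). T cell and interferon response scores had r = 0.579 and rho = 0.557 (0.544 without 2 tumors, 0.545 and 0.627 within the parts). Endothelial and mural scores had r = 0.538 and rho = 0.486 (0.443 without 2 tumors, 0.428 and 0.763 within the parts), a relation that did not pass without the 2 farthest tumors. Erythrocyte and immediate early and stress scores had r = 0.577 and rho = 0.502 (0.556 without 2 tumors, 0.568 and 0.648 within the parts), a relation that did not pass by rho without the 2 farthest tumors. The other 14 pairs had r from 0.444 (neutrophil and hypoxia) to 0.649 (Hippo pathway targets and growth factor receptors). All 22 pairs had a positive r in both parts, while no pair passed within either part. Without the 2 farthest tumors 13 of the 22 passed, and after GC removal 15. The numbers of positive and negative pairs depended on the setting, with 10 and 5 after median ratio rescaling, 17 and 4 after upper quartile rescaling, 18 and 10 after GC removal and 18 and 2 without the 2 farthest tumors.

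**Figure D4:**
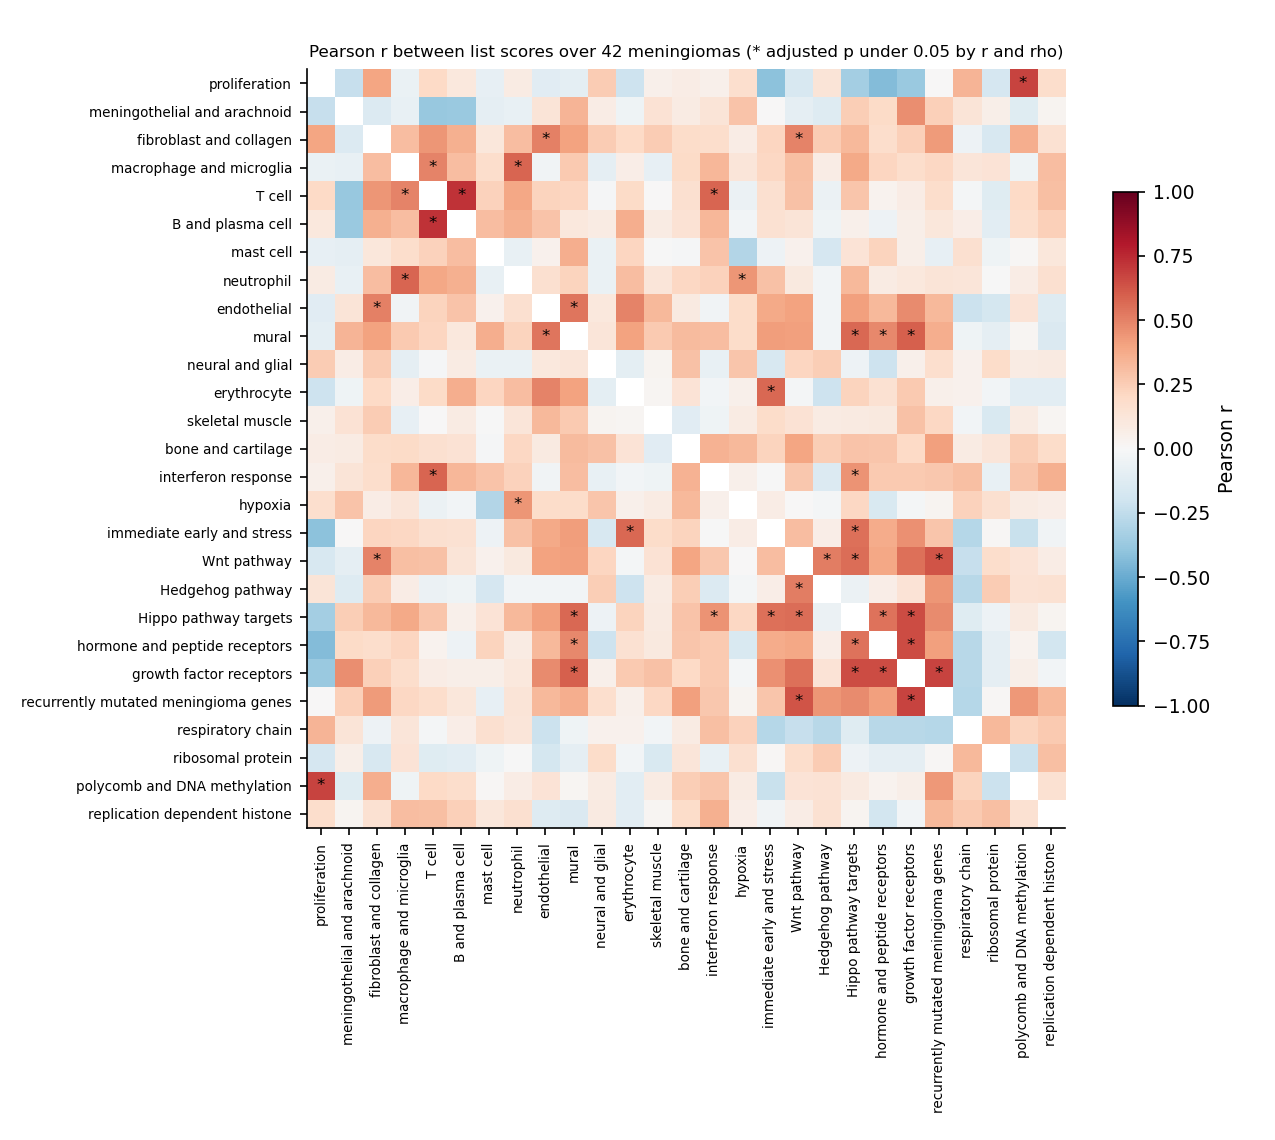
Colours give Pearson's r between the scores of 27 gene lists over 42 tumors, and asterisks mark the 22 pairs past an adjusted p of 0.05 by r and by rho. The T cell and B and plasma cell pair is the strongest at 0.719, with most B and plasma cell genes near the floor.

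In 56 single genes of receptors, signalling pathways and chromatin, UHRF1 and EZH2 went with the proliferation score. UHRF1 had r = 0.903 and rho = 0.795 (adjusted p = 0.000280 for each), 0.833 without the 2 farthest tumors, and 0.882 and 0.924 within the 27 and 15 tumors. EZH2 had r = 0.751 and rho = 0.684 (adjusted p = 0.000280 for each), 0.642 without the 2 farthest tumors, and 0.762 and 0.770 within the parts. No gene passed with a negative sign by both measures, with 7 at an unadjusted permutation p under 0.05, 1 adjusted by r alone and 2 adjusted by rho alone. The Hippo targets CCN1 (r = -0.423, rho = -0.494) and AMOTL2 (r = -0.416, rho = -0.484) passed by rho alone (adjusted p = 0.0178 for each) and missed by r (adjusted p = 0.0533 for each). Without the 2 farthest tumors their r was -0.422 and -0.383, and within the 27 and 15 tumors it was -0.628 and -0.0192 for CCN1 and -0.522 and -0.220 for AMOTL2. The insulin-like growth factor receptor IGF1R passed by r alone (r = -0.482, adjusted p = 0.0148; rho = -0.403, adjusted p = 0.0779; r of -0.406 without 2 tumors, -0.459 and -0.484 within the parts). PGR had r = -0.331 and rho = -0.309 (adjusted p = 0.139 and 0.189). The number of negative genes was 6 after median ratio rescaling and 21 after GC removal. PGR, IGF1R, CCN1 and AMOTL2 were among these 21. After GC removal PGR had r = -0.424 (adjusted permutation p = 0.0161 by r and 0.0102 by rho), so its call depended on the setting.

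Expression of whole chromosomes went with proliferation for none of 23 autosome scores by both measures, with 2 positive at an unadjusted permutation p under 0.05, 0 adjusted by r alone and 2 adjusted by rho alone. Chromosome 21 had rho = 0.603 (adjusted p = 0.00115) and r = 0.421 (adjusted p = 0.161), and 1q had rho = 0.474 (adjusted p = 0.0201) and r = 0.346 (adjusted p = 0.3005). After GC removal, chromosomes 21 (r = 0.577) and 19 (r = 0.473) passed by both.

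**Figure D5:**
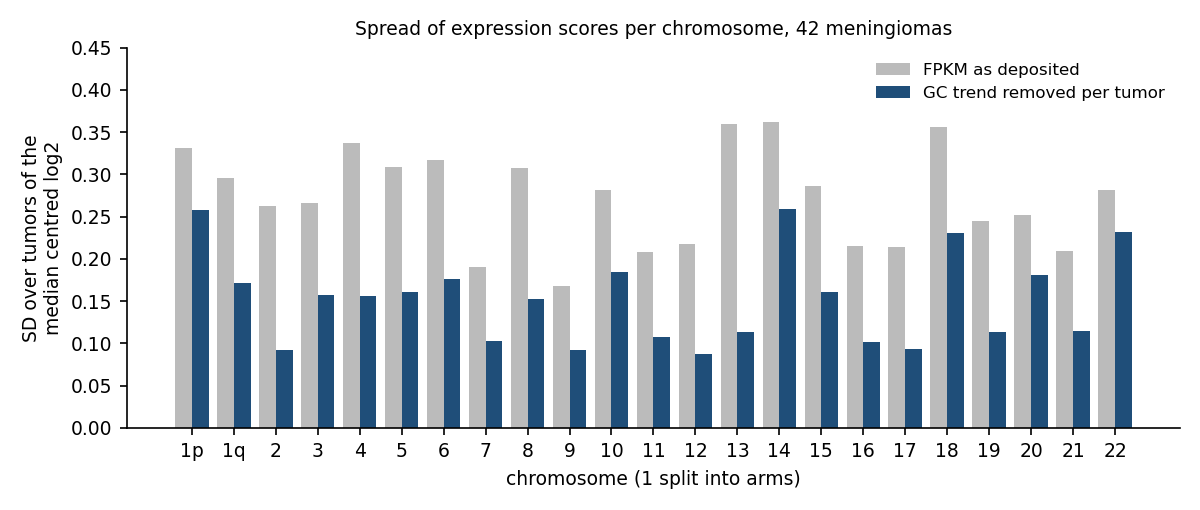
Bars give the SD over 42 tumors of each chromosome score (median centred log2), from FPKM as deposited and after removal of the GC trend. After that removal chromosomes 14 (0.259), 1p (0.258), 22 (0.232) and 18 (0.230) stand highest, while as deposited 8 others lie above the lowest of these 4.

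NF2, a tumor suppressor on chromosome 22, which meningiomas often lose, followed the other 346 chromosome 22 genes moderately. NF2 and their score had r = 0.460 (permutation p = 0.00194) and rho = 0.363 (permutation p = 0.0182) over 42 tumors. Without the 2 farthest tumors r was 0.413 (p = 0.00747) and rho 0.288 (p = 0.0720), so the call by rho did not hold. It was r = 0.512 within the 27 tumors and 0.306 within the 15, where it did not pass (permutation p = 0.265). The median rho of NF2 with single genes was 0.156 on chromosome 22, which ranked 3 among the 23 scores after chromosomes 14 (0.239) and 4 (0.163). Chromosome 22 ranked 1 within the 27 tumors and 13 within the 15. After removal of the GC trend it ranked 1, and its score fell into 2 components, so no pooled r is given there. Within the component of 34 tumors r was 0.137 and rho 0.0717 (permutation p = 0.441 and 0.686), and within that of 8 tumors r was 0.873 and rho 0.952 (exact permutation p = 0.000149 and 0.00114).

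The first principal component took 17.5% of the variance and the next 4 took 6.95%, 6.62%, 5.22% and 4.62%. Of 81 relations with list scores, 12 passed with a positive and 1 with a negative sign. The first component went with Hippo pathway targets (r = 0.798, rho = 0.767, adjusted p = 0.000270 for each; 0.7496 without the 2 farthest tumors), growth factor receptors (r = 0.639, rho = 0.584; 0.617), hormone and peptide receptors (r = 0.601, rho = 0.670; 0.602) and mural genes (r = 0.588, rho = 0.526; 0.502). Wnt pathway, recurrently mutated genes, endothelial and interferon response scores passed as well (r = 0.503, 0.470, 0.469 and 0.417), but not without the 2 farthest tumors. The second component ran against the meningothelial score (r = -0.711, rho = -0.780, adjusted p = 0.000270 for each; -0.771 without 2 tumors) and with macrophage genes (r = 0.449, rho = 0.451), the latter not without the 2 farthest tumors. The third went with recurrently mutated genes (r = 0.590, rho = 0.568; 0.517 without 2 tumors), fibroblast genes (r = 0.392, rho = 0.492; 0.472) and Hedgehog pathway genes (r = 0.541, rho = 0.426), the last not without the 2 farthest tumors.

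Members of 15 of the 24 lists with enough members varied together more than the upper bound of random lists matched on expression. The median pairwise rho was 0.900 for 3 erythrocyte genes, 0.871 for 6 T cell genes, 0.845 for 16 proliferation genes, 0.615 for 13 macrophage genes and 0.610 for 12 interferon response genes. It was 0.140 for meningothelial genes, 0.0717 for recurrently mutated genes and 0.112 for neural and glial genes, which stayed below that bound. Growth factor receptors (0.183), hormone and peptide receptors (0.269) and polycomb and DNA methylation genes (0.223) stayed below it as well. So did mast cell (0.360), neutrophil (0.306) and Hedgehog pathway genes (0.138). These values are across genes, which are not independent replicates.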

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

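Chosen after the results were seen were the settings GC trend removal, accessions counted once, doubtful 0 left out and the 27 and 15 tumor parts, as well as the demand on both r and rho. No paired analysis was possible because all tumors form 1 group. No named relation or slope that passed changed its sign under the settings it was rerun in. Numbers of calls could only stay or move, and for list pairs and single genes negative calls appeared in some settings where the main setting had none. FOXM1 and proliferation passed in each setting, with r from 0.885 to 0.953. Of the alternatives for named results, 374 of 402 passed for FOXM1 genes, 281 of 355 for PGR genes, 141 of 220 for list pairs, 20 of 20 for single genes and 7 of 13 for components. In 100 shuffles of FOXM1 over tumors none called as many genes as the 543 observed (highest 9), and for PGR none reached the 479 observed (highest 1). Depth is unknown and could not be varied.

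For the changes below the cause was not tested, except that fewer tumors or other genes entered the fits without 2 tumors, within the parts and under other filters. Counting a gene from 0.1 FPKM gave a median of 16127 genes and from 5 FPKM 8122. With a pseudocount of 0.1, 11 of the 20 most variable genes were shared, list pairs had 1 negative, single genes 2 negative and PGR 216 negative. With 0.01 these were 11, 1, 2 and 195, and PC1 took 14.5%. Upper quartile rescaling gave 4 negative pairs, 3 negative single genes, 1 chromosome with proliferation, 5 lists with PC1, FOXM1 628 positive and 388 negative, and PGR 185 negative. Median ratio rescaling gave 10 positive and 5 negative pairs, 6 negative single genes, 1 chromosome, 4 lists with PC1, FOXM1 1008 positive and 648 negative, PGR 170 positive, and r = 0.389 for NF2 with chromosome 22, where rho did not pass (permutation p = 0.0642). GC removal gave 10 negative pairs, 6 positive and 21 negative single genes, 2 chromosomes, a PC1 share of 13.3%, FOXM1 648 positive and 402 negative, and PGR 87 positive and 24 negative. It shared 342 and 104 of the FOXM1 calls and 81 and 12 of the PGR calls.

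Within the 27 tumors there were 0 pairs, 1 negative single gene, a PC1 share of 13.5%, 4 lists with PC1, FOXM1 190 positive and 36 negative, and PGR 40 positive and 7 negative. Within the 15 tumors there were 0 pairs, r = 0.306 for NF2 (permutation p of rho = 0.506), a PC1 share of 26.9%, 4 lists with PC1, FOXM1 79 positive and 0 negative, and PGR 0 and 0. Without the 2 farthest tumors there were 2 negative pairs, r = 0.413 for NF2 (permutation p of rho = 0.0720), 4 lists with PC1, FOXM1 163 positive and 43 negative, and PGR 200 positive and 58 negative. No filter gave a PC1 share of 15.2%, FOXM1 765 positive, and PGR 208 positive and 59 negative, and the filter of 21 tumors a PC1 share of 19.7%. PC1 as a covariate gave FOXM1 669 positive and 65 negative, and PGR 43 positive and 10 negative. With an estimated correlation, camera placed 1 list upward and 0 downward. No pooled value is printed for NF2 with chromosome 22 after GC removal, because that score had 2 components, and the values within them stand in the report.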

Other observations

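Chosen after the result was seen were the relations of FOXM1 with list scores, the choice of the 4 chromosome scores and their GC tests, the tests of GC content, transcript length and number of genes detected for PC1 and for slopes on PGR, and the test of low expression behind values of 0. In tumors with more FOXM1 the hormone and peptide receptor score was lower (r = -0.455, rho = -0.457, permutation adjusted p = 0.0127 and 0.0144 over 27 relations; -0.437 without the 2 farthest tumors, -0.312 within the 27 tumors and -0.657 within the 15). The immediate early and stress score was lower as well (r = -0.4995, rho = -0.520, adjusted p = 0.00810 and 0.00540; -0.554 without 2 tumors, -0.596 and -0.313 within the parts), as was the Hippo target score (r = -0.469, rho = -0.496, adjusted p = 0.0125 and 0.00601; -0.431, -0.625 and -0.242). Immediate early genes went with the erythrocyte score over tumors, and their r with FOXM1 given that score was -0.444. FOXM1 also had r = -0.315 with PC1 (permutation p = 0.0415). PC1 in turn had r = 0.601 with the hormone and peptide receptor score and 0.798 with the Hippo target score. The relations of FOXM1 with list scores were not adjusted for PC1.

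Genes of neighbouring tissues were low in most tumors. GFAP, the astrocyte filament, had a median of 0.399 FPKM and a highest value of 1696 FPKM, and the synaptic gene SNAP25 a median of 0.0843 FPKM and a highest value of 250 FPKM. Among the 12 neural and glial genes, GAP43 (14.8 FPKM) and the myelin gene MBP (4.89 FPKM) had the highest medians. Skeletal muscle genes were near 0, with TNNT3 highest at a median of 0.804 FPKM. In the bone and cartilage list COL2A1 had a median of 23.1 FPKM and reached 1 FPKM in 40 tumors. The mast cell tryptase TPSB2 had a median of 2.50 FPKM and a highest value of 275 FPKM.

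After removal of the GC trend the scores of chromosomes 14 (SD 0.259), 1p (0.258), 22 (0.232) and 18 (0.230) spread more than the other 19, of which the highest SD was 0.184, but as deposited 8 of the others lay above the lowest of these 4 (0.282). A stretch confined to 1 part of the arm is argued against by the r between its lower and upper part, at least 0.762. Such an r is not particular to these 4, as it reached 0.892 among the others, and picking arms for their spread can raise it. A few genes can hardly move a median over a whole arm, so this r does not bear on them. For 1p, 14 and 22 the SDs as deposited were at least 1.29 times the upper bound of 1000 GC-matched sets of genes of other chromosomes. Chromosome 18 (1.17) lay between the bounds set, and 5 of the other scores passed the same bound of 1.2. The 4 were picked for their spread after GC removal, which favors such ratios. This test therefore cannot decide on GC content as the whole cause, which stays open for all 4. Gene dosage along the whole arm may contribute. Genes of these arms followed the rest of their arm with a median rho of at least 0.370 against at most 0.294 elsewhere. However, the arms were picked for their spread, which raises that value by itself, so dosage stays open. No other biological explanation was tested.

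PC1 may reflect the GC content of genes: across genes, which are not independent replicates, its loadings had rho = -0.676 with GC content, and slopes on PGR and on FOXM1 had -0.543 and 0.316. For the slopes on PGR this stays open, as removal of the GC trend left a median of 0.699 of the slope (quartiles 0.550 and 0.834) in 458 called genes, none with another sign, just under the bound of 0.7 set against it. The median size of these slopes went from 0.40 (median SE 0.11) to 0.28 (median SE 0.09), so 93 passed after removal, among them SCARA5 (1.19, SE 0.19, before and 1.25, SE 0.20, after), while DAPL1 (1.38, SE 0.40, and 1.27, SE 0.41) did not. Transcript length is argued against for PC1 (partial rho of 0.137 once GC was taken out), and the number of genes detected stays open (rho = 0.453 over tumors, between the bounds set), as does a batch, since PC1 had rho = 0.405 with SNORD141A (permutation p = 0.00815). No biological explanation was tested.

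Values of 0 in abundant genes may come from reads of overlapping genes given to 1 of them. In a set of 94 genes at 0 in at least 5 tumors and with a median above 0 of at least 10 FPKM, 90.4% overlapped another gene against 45.1% of 4988 other protein-coding genes, a ratio of 2.01 (Fisher's exact p = 4.68e-20). EIF3C, in this set, overlaps no other gene and ran opposite to its near copy EIF3CL (rho = -0.709, SDs of 3.20 and 1.34, 0.47 for their sum), so overlap does not cover it, and reads shared between copies were not tested over the set. Low expression is argued against by the lowest values above 0 (median 7.54 FPKM, quartiles 5.21 and 12.2), of which 2.13% lay under 1 FPKM. The choice of the genes does not bound these lowest values but favors higher ones, and other genes were not compared. Tumors with fewer genes detected as the cause are argued against by rho = 0.0896. No biological explanation was tested.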
